A study of Mus musculus with 9 samples.

How the data were processed

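RNA of 3 sorted populations, each with 3 biological replicates, was measured on an Affymetrix mouse expression array with 45101 probe sets. Per the labels, total RNA was amplified before hybridisation, and the embryos were of mixed CBA x C57BL/6 background. The deposited values are log2 probe-set levels made by the authors with RMA in the affy package, without version numbers, which also scales the arrays to each other. Values on all arrays lay in that log2 range, no further centring was seen, and no other columns were used here. Array data hold no counts, so no depth per sample can be given. The values carry no detection calls, so it is unknown which dim levels lie above background, and no fold is given where the mean of a population lay near the 25th percentile of the arrays (3.77 to 4.25).

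Probe sets were assigned to genes by the platform's annotation table. Those with 1 gene symbol (34958) were kept, and those with several (932) or none (9211) were left out. Of the kept ones, 34754 carry a gene identifier present in the RefSeq gene table. For each of 18194 genes the probe set with the highest mean over all 9 arrays was used, a choice that concerns 9012 genes with more than 1 probe set. Each gene was fitted with limma 3.58.1 in R 4.3.3 with a mean per population over all 9 arrays (6 residual degrees of freedom), and the 3 comparisons and a moderated F-test over the populations were tested with eBayes. P-values were adjusted by Benjamini-Hochberg over all genes within a comparison, with a threshold of 0.05 (called, or passed). Errors are SEs from limma and intervals are 95% confidence intervals without adjustment. Genes highest or lowest in 23GFP+ EC passed both comparisons of that population in the same sense.

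A set of 28 gene lists (484 symbols, 457 measured) was tested with limma's camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. The lists are sorting markers and reporter gene, endothelial identity, arterial and Notch, venous and lymphatic, haemogenic endothelium, haematopoietic transcription factors, pan-haematopoietic signalling and cytoskeleton, erythroid, megakaryocyte and platelet, myeloid, haem synthesis and iron uptake, cell cycle, nucleolus and Myc targets, glycolysis, BMP and TGF-beta signalling, basement membrane and matrix, cell junctions, Hox genes, interferon and inflammatory, immediate early and dissociation stress, endocardium, cardiomyocyte, mesenchyme and mesoderm, yolk sac endoderm, neural ectoderm, epithelium and trophoblast, pluripotency and germ cells, and Y-linked and Xist. Counts of list members are given over all genes tested and adjusted over the list alone. The lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The rule takes the 4 sorting markers, the 10 largest rises and falls per comparison among called genes whose arrays do not overlap between the groups, up to 4 called members of each list (or the 2 with the smallest p where none was called), and up to 10 genes highest and 10 lowest in 23GFP+ EC. Clone names were skipped in the ranked parts, and genes outside the rule are said to have been chosen after their values were seen.

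The position of 23GFP+ EC was computed per gene as its difference from 23GFP- EC divided by that of CD41+ HPC from 23GFP- EC, over called genes with a log2 difference of at least 1 between the ends. The fit was tested on simulated data with 200 changed genes. At log2 changes of 1, 2 and 3 it recovered 22.4, 85.1 and 98.5 percent of them in 23GFP+ EC against 23GFP- EC, with 4 false calls among 141. The shares were 16.4, 88.1 and 100 percent in CD41+ HPC against 23GFP+ EC (5 of 141 calls false) and 20.9, 91.0 and 100 percent in CD41+ HPC against 23GFP- EC (8 of 149). Simulated noise, here and for the positions, was independent between genes and had the same spread in every population. The real arrays need not be so, and the shares and false calls hold for that setting only.

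The alternatives were the replicate number as a block, somite stage as a term, each array centred on its median, cyclic loess, leaving out the 40 percent of genes with the lowest means, eBayes with trend and robust, array weights, the mean of all probe sets of a gene, only probe sets without a suffix for shared sequence, a log2 change of at least 1, only the 2 groups compared, and leaving out each array in turn. For positions, ends that differ by at least 2 and ends measured on arrays not used to choose the genes were also tried. Leaving out the 2 arrays of narrowest spread was added after seeing the data. A pseudocount did not apply to log2 values. A count was taken as unchanged within 1.5 times its value, a gene or list as changed where its call was gained or lost, and a position as unchanged within 1 SD over the 3 arrays of 23GFP+ EC. Whether the replicate numbers pair the arrays is unknown. After removing group means, 2 of 9 pairs of arrays with the same number correlated above 0.1 (range -0.514 to 0.564). Such correlations cannot exclude shared pools of embryos, and arrays with the same number share a somite range. The block stands only among the alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.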

Results

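RNA levels were measured in 3 cell populations sorted from pooled mouse embryos at embryonic day 8.5 that carry the 23GFP transgene, a green fluorescent reporter. The labels do not name its driver, which from knowledge outside them is an enhancer of the haematopoietic gene Runx1. 23GFP- EC and 23GFP+ EC are endothelial cells (VE-cadherin-positive, with Ter119, CD45 and CD41 absent) without and with reporter fluorescence. CD41+ HPC are haematopoietic cells that still carry VE-cadherin, with the reporter on and CD41 on the surface. Each population has 3 arrays, 1 per biological replicate. Replicate 1 of each came from embryos with 7 to 11 somite pairs, and replicates 2 and 3 from embryos with 4 to 9. The median log2 level lay between 5.29 and 5.38 on all 9 arrays, and the number of arrays limits the precision. Mean correlations with the other arrays of the same group were 0.988 to 0.989 in 23GFP- EC, 0.947 to 0.969 in 23GFP+ EC and 0.967 to 0.974 in CD41+ HPC. The median r of pairs was 0.957 within 23GFP+ EC and 0.969 within CD41+ HPC, against 0.960 and 0.970 of each with 23GFP- EC. Between 23GFP+ EC and CD41+ HPC it was 0.945. By these medians, arrays of 23GFP+ EC and CD41+ HPC did not correlate more with their own group than with 23GFP- EC. The arrays of 23GFP+ EC replicate 2 and CD41+ HPC replicate 1 had the narrowest spread of levels, with SDs of 2.26 and 2.33 (up to 2.56 on the others). The former correlated least with the other 8 arrays (mean r 0.938, against 0.951 to 0.971). It also had the largest difference between the 3' and 5' control probe sets of Gapdh, a measure of RNA quality, at 4.10 (2.11 to 3.28 on the others), and the lowest array weight, 0.235. For the beta-actin control that array's difference was 0.247, within the range of the others (-0.0822 to 0.394). Differences are given as log2 ± SE from limma, with 3 arrays per group.

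The first comparison, 23GFP+ EC against 23GFP- EC, asked which genes the reporter-positive endothelium expresses differently before CD41 is on the surface. Hba-x, an embryonic globin gene, was 25.2-fold lower in 23GFP+ EC (-4.66 ± 0.45, adjusted p = 0.00114). Klf1, an erythroid transcription factor, differed by -3.32 ± 0.39 (adjusted p = 0.00274). The scavenger and hyaluronan receptors Stab2 and Lyve1 were 24.8-fold (-4.63 ± 0.35, adjusted p = 0.00034) and 13.9-fold lower (-3.79 ± 0.37, adjusted p = 0.0012). Prl4a1, of the placental prolactin family, was higher in 23GFP+ EC by 4.85 ± 0.37 (adjusted p = 0.00034), with mean levels of 8.94 there and 4.08 in 23GFP- EC, the latter near the 25th percentile of the arrays (3.77 to 4.25). Also higher were Hoxa9 (3.65 ± 0.35, adjusted p = 0.00114), Tbx4, a T-box factor of the allantois and hindlimb mesoderm (3.63 ± 0.31, adjusted p = 0.000678), and Krt8, an epithelial keratin (2.79 ± 0.32, adjusted p = 0.00223). Of 18194 genes tested, 433 passed, 208 higher and 225 lower in 23GFP+ EC, and 422 of them differed at least 2-fold. The count was 119, 131 or 216 without 23GFP- EC replicate 1, 2 or 3, 256 without 23GFP+ EC replicate 3, and 1259 with array weights. A fit of the arrays of these populations alone gave 325. The share of called genes that were higher, 48.0 percent, became 41.2 to 59.2 percent over the alternatives, and lay above 50 percent without 23GFP+ EC replicate 1 (59.2) or 3 (50.4). Of 48 called genes followed through the alternatives, 19 were called in all of them. Calls were lost in 25, 26 and 16 without 23GFP- EC replicates 1, 2 and 3, and 14 without 23GFP+ EC replicate 3, beside 1 to 6 without any other array, and in 9 with a replicate block. Among genes named for this comparison, Gata1 (3.94), Plek (3.98) and Ikzf1 (4.11) in 23GFP+ EC, Fga (3.58) and Zfp42 (3.64) in 23GFP- EC and Ptprc in both (3.44 and 3.03) had mean levels under 4.25, the highest 25th percentile of an array. Their differences, like that of Prl4a1, are against levels not known to lie above background. Of 34 called genes under the naming rule with several probe sets, 15 had another one with under 0.5 of the difference used. Of the genes given here these are Cd53, Cd93, Hand1, Hoxa10, Ikzf1, Pdgfra, Spn, Tbx4 and Tgfbr2, and in Cd53 and Tgfbr2 the sign turned (0.38 and 0.27).

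Of the sorting markers and Runx1, none was called by limma. Runx1 stood at 7.18 ± 0.36 (SD, n = 3) in 23GFP+ EC and 7.47 ± 0.30 (SD, n = 3) in 23GFP- EC. The difference was -0.30 ± 0.28, with a 95% confidence interval of -0.92 to 0.33 (adjusted p = 0.836). Its 6 probe sets gave differences between -0.47 and 0.33. Cdh5, which encodes VE-cadherin, differed by -0.75 ± 0.27 (adjusted p = 0.269), Itga2b, which encodes CD41, by -0.56 ± 0.21 (adjusted p = 0.298) and Ptprc, which encodes CD45, by 0.41 ± 0.56 (adjusted p = 0.903). By limma, 0 of these 4 passed over all genes tested and 2 were lower adjusted over the list alone (camera adjusted p = 0.0572; adjusted p = 0.384 with an estimated correlation). The list passed as lower without 23GFP- EC replicate 3 (adjusted p = 0.0369) or 23GFP+ EC replicate 2 (adjusted p = 0.0208) or the dimmest 40 percent of genes (adjusted p = 0.0472), and Itga2b with array weights (adjusted p = 0.0311).

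Among endothelial identity genes, 3 of 25 were lower in 23GFP+ EC over all genes tested and 11 adjusted over the list alone, and 24 of the 25 differences were below 0, with a median of -0.90. The list passed camera (adjusted p = 2.00e-13; adjusted p = 0.108 with an estimated correlation). Clec14a, Cd93 and Robo4, endothelial surface receptors, differed by -2.72 ± 0.45 (adjusted p = 0.0127), -2.04 ± 0.38 (adjusted p = 0.0199) and -1.79 ± 0.30 (adjusted p = 0.0142). Of the venous and lymphatic genes, 3 of 11 were lower over all genes, and 5 were lower and 1 higher adjusted over the list alone (camera adjusted p = 9.65e-07; adjusted p = 0.0837 with an estimated correlation). These were Stab2, Lyve1 and Stab1 (-1.85 ± 0.31, adjusted p = 0.0128). In the arterial and Notch list 1 of 19 genes was called, Jag1, a Notch ligand that was higher by 2.08 ± 0.25 (adjusted p = 0.00274). Adjusted over the list alone, 2 were higher and 2 lower (camera adjusted p = 0.0572; adjusted p = 0.196 with an estimated correlation). Cell junction genes had 0 of 23 called by limma over all genes and 0 adjusted over the list alone. With a median of -0.38 and 19 of 23 differences below 0, the list was lower by camera (adjusted p = 0.000166; adjusted p = 0.199 with an estimated correlation). Clec14a, Cd93 and Stab1 lost their calls without single arrays, with adjusted p of up to 0.0794, 0.108 and 0.0794 without 23GFP- EC replicate 1, and Robo4 with up to 0.0777 without 23GFP- EC replicate 2. The arterial list passed as lower without 23GFP- EC replicate 3 (adjusted p = 0.0410), 23GFP+ EC replicate 1 (adjusted p = 0.0306) or CD41+ HPC replicate 2 (adjusted p = 0.0468), and with a replicate block (adjusted p = 0.0450).

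Erythroid genes were lower in 23GFP+ EC: 6 of 20 over all genes tested and 16 adjusted over the list alone (median -1.48, camera adjusted p = 2.14e-17; adjusted p = 0.0699 with an estimated correlation). Besides Hba-x and Klf1 they included Hbb-bh1, another embryonic globin gene (-2.94 ± 0.43, adjusted p = 0.00719), and Gata1, a transcription factor of erythroid and megakaryocytic cells (-2.42 ± 0.37, adjusted p = 0.00877). Of the haematopoietic transcription factors, 6 of 21 were lower over all genes and 9 adjusted over the list alone (camera adjusted p = 5.76e-07; adjusted p = 0.0898 with an estimated correlation). Klf1 and Gata1 are among these lower genes too, so the erythroid list and this one are not separate. Ikzf1, a lymphoid and haematopoietic zinc-finger factor, differed by -2.28 ± 0.38 (adjusted p = 0.0139). In the pan-haematopoietic list of signalling and cytoskeletal genes, 5 of 23 were lower and 1 was higher over all genes, and 6 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00113; adjusted p = 0.249 with an estimated correlation). Plek, a substrate of protein kinase C in blood cells, differed by -2.56 ± 0.37 (adjusted p = 0.00641) and Cd53, a leukocyte tetraspanin, by -2.35 ± 0.25 (adjusted p = 0.0016). Spn, a leukocyte sialoglycoprotein, was higher by 3.08 ± 0.42 (adjusted p = 0.00498) on the probe set used and by 0.36 on its other one. With the mean of all probe sets of a gene Cd53 did not pass (adjusted p = 0.0883). Endothelial genes had a median of -0.90 on the same arrays.

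Haemogenic endothelium genes had 2 of 16 lower over all genes and 4 adjusted over the list alone, with a median of -0.06 (camera adjusted p = 0.0268; adjusted p = 0.40 with an estimated correlation). They were Gfi1b, a transcriptional repressor (-1.79 ± 0.39, adjusted p = 0.0395), and Procr, the endothelial protein C receptor (-1.30 ± 0.24, adjusted p = 0.0187). Megakaryocyte and platelet genes had 1 of 19 lower over all genes, Plek, and 3 adjusted over the list alone (camera adjusted p = 0.00789; adjusted p = 0.273 with an estimated correlation). The myeloid list did not pass (camera adjusted p = 0.0572; adjusted p = 0.331 with an estimated correlation), and its median of 0.09 and mean of -0.34 differed in sign. Its called genes, 2 of 19 over all genes and 2 adjusted over the list alone, were lower and included Mrc1, the macrophage mannose receptor (-3.60 ± 0.39, adjusted p = 0.00208). Without 23GFP+ EC replicate 3 the haemogenic list (adjusted p = 0.146) and the megakaryocyte list (adjusted p = 0.0521) no longer passed, nor did the former without 23GFP- EC replicate 2 (adjusted p = 0.105) or the dimmest 40 percent of genes (adjusted p = 0.276). The myeloid list passed as lower without 23GFP- EC replicate 2 or 3 (adjusted p = 0.0474 and 0.0369) or 23GFP+ EC replicate 2 (adjusted p = 0.00674), or without the dimmest 40 percent of genes (adjusted p = 0.00426). Ikzf1, Gfi1b and Procr lost their calls without single arrays, with adjusted p of up to 0.0584, 0.176 and 0.108 without 23GFP- EC replicate 2.

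Yolk sac endoderm and epithelial genes were higher in 23GFP+ EC. All 17 measured endoderm genes had differences above 0 (median 2.38). Of them 7 passed over all genes and 17 adjusted over the list alone (camera adjusted p = 5.08e-17; adjusted p = 0.134 with an estimated correlation). Their mean log2 level was 9.97 ± 1.27 (SD, n = 3) in 23GFP+ EC, 7.60 ± 0.49 (SD, n = 3) in 23GFP- EC and 5.79 ± 0.36 (SD, n = 3) in CD41+ HPC. In the 3 arrays of 23GFP+ EC their median levels were 9.37, 9.89 and 11.8 for replicates 1, 2 and 3. Apob and Apom, which encode apolipoproteins, Fga, a fibrinogen chain, and Cubn, an endocytic receptor, were higher by 3.08 ± 0.62, 2.82 ± 0.53, 3.05 ± 0.61 and 2.88 ± 0.58 (adjusted p = 0.0276, 0.0204, 0.0283 and 0.0286). Of 9 epithelium and trophoblast genes, 6 were higher over all genes and 7 adjusted over the list alone (median 2.34, camera adjusted p = 2.24e-12; adjusted p = 0.0699 with an estimated correlation). They included Tfap2c, a trophoblast transcription factor (27.8-fold, 4.80 ± 0.94, adjusted p = 0.0257), Epcam, an epithelial adhesion molecule (2.57 ± 0.41, adjusted p = 0.0108), and Krt7, a simple-epithelium keratin (2.34 ± 0.43, adjusted p = 0.0197), besides Krt8. Of these genes Krt8 kept its call without any 1 array. The others lost theirs, with adjusted p of up to 0.137 for Apob, 0.112 for Apom, 0.137 for Fga, 0.133 for Cubn, 0.133 for Tfap2c and 0.0687 for Epcam without 23GFP- EC replicate 1, and 0.108 for Krt7 without 23GFP- EC replicate 2. On probe sets without a suffix for shared sequence Apom and Cubn did not pass (adjusted p = 0.114 and 0.288), nor did Apob and Cubn with the mean of all probe sets (adjusted p = 0.0508 and 0.0889).

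The Hox list and the mesenchyme and mesoderm list passed camera as higher in the same population, on arrays where endoderm genes were also higher. In the Hox list, 17 of 23 differences were above 0 and 6 below, 6 genes were higher over all genes tested, and 9 were higher and 2 lower adjusted over the list alone (median 0.58, camera adjusted p = 6.92e-05; adjusted p = 0.0699 with an estimated correlation). Besides Hoxa9 they included Hoxa10 (3.30 ± 0.36, adjusted p = 0.0022), Hoxd9 (2.68 ± 0.50, adjusted p = 0.0197) and Hoxc8 (2.57 ± 0.32, adjusted p = 0.00315). The other probe sets of Hoxa9, Hoxa10 and Tbx4 gave 2.01, 0.58 and 1.5, and that of Hoxa10 did not pass in its place (adjusted p = 0.554). Of 18 mesenchyme and mesoderm genes, 17 had differences above 0 and 1 below (median 0.40). Of them 3 were higher over all genes, and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.09e-05, and adjusted p = 0.0867 with an estimated correlation). They were Tbx4, Pdgfra, a growth factor receptor of mesenchyme (1.80 ± 0.30, adjusted p = 0.0136), and Hand1, a transcription factor of extraembryonic and lateral mesoderm (1.72 ± 0.26, adjusted p = 0.00827). Hoxd9 and Pdgfra lost their calls without single arrays, with adjusted p of up to 0.102 and 0.0838 without 23GFP- EC replicate 1, and Hand1 without 23GFP- EC replicate 2 (adjusted p = 0.0549).

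Of 20 BMP and TGF-beta genes 1 was lower over all genes, Tgfbr2, a TGF-beta receptor (-1.5 ± 0.29, adjusted p = 0.0249). Adjusted over the list alone 4 were higher and 7 lower (camera adjusted p = 0.102; adjusted p = 0.273 with an estimated correlation). Basement membrane and matrix genes were lower as a list (median -0.40, camera adjusted p = 0.00719; adjusted p = 0.447 with an estimated correlation). The only 1 of its 15 called over all genes, Lamb1, a laminin chain, was higher (1.12 ± 0.24, adjusted p = 0.0421), and 1 was higher and 3 lower adjusted over the list alone. Nucleolus and Myc target genes were higher as a list (camera adjusted p = 0.00459; adjusted p = 0.248 with an estimated correlation). Of the 15, 1 was called over all genes and adjusted over the list alone, Myc itself (1.16 ± 0.25, adjusted p = 0.0401). Of 8 endocardium genes 1 was lower over all genes and adjusted over the list alone, Npr3, a natriuretic peptide receptor (-1.76 ± 0.30, adjusted p = 0.0152). That list did not pass (camera adjusted p = 0.276; adjusted p = 0.384 with an estimated correlation), and its median of 0.01 and mean of -0.21 differed in sign. Without 23GFP+ EC replicate 2 the matrix list had an adjusted p of 0.367, and the nucleolus list had 0.0592 without 23GFP+ EC replicate 3 and 0.0509 without 23GFP+ EC replicate 1. Tgfbr2 and Lamb1 lost their calls without single arrays, with adjusted p of up to 0.134 and 0.171 without 23GFP- EC replicate 2. The same held for Myc and Npr3, with up to 0.192 and 0.0885 without 23GFP- EC replicate 1. With the mean of all probe sets Tgfbr2 and Lamb1 did not pass (adjusted p = 0.253 and 0.0683), nor did Lamb1 on probe sets without a suffix (adjusted p = 0.0978). With an estimated correlation, 0 of the 28 lists passed camera in this comparison, and 8 had an unadjusted p under 0.05.

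The second comparison, CD41+ HPC against 23GFP+ EC, asked what changes when reporter-positive cells carry CD41 on their surface. Runx1 was 10.7-fold higher in CD41+ HPC (3.42 ± 0.28, adjusted p = 8.89e-05) on the probe set used, and its other 5 probe sets gave 3.84, 2.30, 0.85, 0.71 and 0.67. Myb, a transcription factor of haematopoietic progenitors, was 37.9-fold higher (5.24 ± 0.30, adjusted p = 2.3e-05). Plek was higher by 6.73 ± 0.37 (adjusted p = 2.06e-05) and Klf1 by 5.27 ± 0.39 (adjusted p = 5.94e-05), with mean levels of 10.7 and 9.56 in CD41+ HPC and of 3.98 and 4.28 in 23GFP+ EC, near the 25th percentile of the arrays. Apob was 63.8-fold lower in CD41+ HPC (-6.00 ± 0.62, adjusted p = 0.000358) and Ttr, the thyroid hormone carrier transthyretin, 44.8-fold lower (-5.49 ± 0.55, adjusted p = 0.000324). Both are in the endoderm list, for which endoderm cells or free RNA in the 23GFP+ EC sort remain a candidate source. Also lower were Tbx3, a T-box factor (-5.12 ± 0.36, adjusted p = 5.94e-05), and Jag1 (12.1-fold, -3.60 ± 0.25, adjusted p = 5.94e-05). Of 18194 genes 835 passed, 317 higher and 518 lower in CD41+ HPC, and 803 of them differed at least 2-fold. The count was 595 to 867 without 1 array, 452 in a fit of these 6 arrays alone and 1289 with array weights. The share of called genes that were higher was 33.1 to 42.8 percent over the alternatives (38.0 percent here). Of 57 called genes followed through the alternatives, 42 were called in all of them. Leaving out 1 array ended at most 7 of these calls (CD41+ HPC replicate 3), and a replicate block ended 5. Mean levels under 4.25 were those of Gfi1 (3.24), Ptprc (3.44), Tubb1 (3.74), Gata1 (3.94), Plek (3.98), Ikzf1 (4.11), Nfe2 (4.15) and Tyrobp (4.18) in 23GFP+ EC. In CD41+ HPC they were those of Hoxa10 (3.32), Zfp42 (3.85), Tbx3 (4.01), Cdh1 (4.03) and Prl4a1 (4.18), and the differences of all these genes are against levels not known to lie above background. Of 53 called genes under the naming rule with several probe sets, 32 had another one with under 0.5 of the difference used. Of the genes given here these are Csf1r, F5, Fermt3, Hoxa9, Hoxa10, Id2, Ikzf1, Jag1, Lamb1, Ncam1, Npr3, Nr2f2, Rab27b, Runx1, Socs3, Sox7, Sox17, Tbx3, Tbx4, Tgfb2, Tnnt2 and Uros, and in Ncam1 and Tnnt2 the sign turned (up to 0.19 and 0.21).

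Of the 4 sorting markers and reporter genes, 2 were higher in CD41+ HPC over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00019; adjusted p = 0.0918 with an estimated correlation). Itga2b was higher by 1.13 ± 0.21 (adjusted p = 0.0123), Ptprc differed by 2.20 ± 0.56 (adjusted p = 0.0552) and Cdh5 by -0.25 ± 0.27 (adjusted p = 0.82). Haemogenic endothelium genes had 7 of 16 higher and 1 lower over all genes, and 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.13e-12; adjusted p = 0.0306 with an estimated correlation). Gfi1 and Gfi1b, related repressors, were higher by 4.64 ± 0.40 (adjusted p = 0.00011) and 3.95 ± 0.39 (adjusted p = 0.000273). The lower one was Sox17, an endothelial transcription factor (-1.95 ± 0.31, adjusted p = 0.00425). Of 21 haematopoietic transcription factors, 9 were higher over all genes and 13 adjusted over the list alone (camera adjusted p = 7.79e-14; adjusted p = 0.0176 with an estimated correlation). Ikzf1 was higher by 5.03 ± 0.38 (adjusted p = 6.28e-05) and Gata1 by 4.92 ± 0.37 (adjusted p = 5.94e-05). In the pan-haematopoietic list 11 of 23 were higher over all genes and 16 adjusted over the list alone (camera adjusted p = 4.78e-17; adjusted p = 0.0176 with an estimated correlation). Fermt3, an integrin activator of blood cells, differed by 3.52 ± 0.32 (adjusted p = 0.000177), and on probe sets without a suffix for shared sequence it did not pass (adjusted p = 0.106). Leaving out 23GFP+ EC replicate 2 or CD41+ HPC replicate 3 took Ptprc past the threshold (adjusted p = 0.0189 and 0.0134), and a fit of these 6 arrays alone ended the call of Itga2b (adjusted p = 0.0629).

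Blood lineage genes were higher in CD41+ HPC in all 3 lists tested. Erythroid genes had 12 of 20 higher over all genes and 15 adjusted over the list alone (camera adjusted p = 2.18e-20; adjusted p = 0.0165 with an estimated correlation). Hba-x was higher by 5.20 ± 0.45 (adjusted p = 0.00012), Nfe2, a globin-activating transcription factor, by 4.67 ± 0.24 (adjusted p = 2.06e-05) and Hbb-bh1 by 3.35 ± 0.43 (adjusted p = 0.00136). Megakaryocyte and platelet genes had 7 of 19 higher over all genes and 9 adjusted over the list alone (camera adjusted p = 1.69e-12; adjusted p = 0.0182 with an estimated correlation). Tubb1, the platelet tubulin, was higher by 4.76 ± 0.39 (adjusted p = 8.89e-05), Rab27b, a GTPase of platelet granules, by 4.21 ± 0.28 (adjusted p = 5.7e-05) and Itgb3, the partner of CD41 in the fibrinogen receptor, by 3.90 ± 0.51 (adjusted p = 0.00145). Myeloid genes had 8 of 19 higher over all genes and 9 adjusted over the list alone (camera adjusted p = 5.44e-10; adjusted p = 0.0176 with an estimated correlation). They included Csf1r, a macrophage growth factor receptor (4.31 ± 0.43, adjusted p = 0.000294; 1.97 and 0.25 on its other probe sets), and Tyrobp, a signalling adaptor of myeloid cells (4.12 ± 0.45, adjusted p = 0.000504).

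Endoderm and epithelial genes, higher in 23GFP+ EC in the first comparison, were lower in CD41+ HPC. Endoderm cells or free RNA in the 23GFP+ EC sort would give the same direction for the endoderm genes. Of 17 endoderm genes 16 were lower over all genes and 17 adjusted over the list alone (camera adjusted p = 5.48e-27; adjusted p = 0.0324 with an estimated correlation). Of 9 epithelium and trophoblast genes 6 were lower over all genes and 7 adjusted over the list alone (camera adjusted p = 7.09e-13; adjusted p = 0.0182 with an estimated correlation). Cdh1, which encodes E-cadherin, differed by -4.89 ± 0.70 (adjusted p = 0.00242), Krt8 by -3.94 ± 0.32 (adjusted p = 8.2e-05) and Tfap2c by -5.05 ± 0.94 (adjusted p = 0.0121). The Hox list had 8 of 23 lower over all genes and 10 adjusted over the list alone (camera adjusted p = 1.35e-11; adjusted p = 0.0118 with an estimated correlation). Hoxa10 differed by -4.84 ± 0.36 (adjusted p = 5.94e-05) and Hoxa9 by -4.35 ± 0.35 (adjusted p = 8.2e-05). Mesenchyme and mesoderm genes had 7 of 18 lower over all genes and 12 adjusted over the list alone (camera adjusted p = 2.79e-12; adjusted p = 0.0118 with an estimated correlation). Tbx4 differed by -3.95 ± 0.31 (adjusted p = 7.38e-05) and Foxc2, a mesodermal forkhead factor, by -3.71 ± 0.31 (adjusted p = 8.98e-05). The call of Tfap2c ended without CD41+ HPC replicate 3 (adjusted p = 0.0574), and that of Hoxa10 on its other probe set (adjusted p = 0.801).

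The arterial and Notch list had 4 of 19 lower in CD41+ HPC over all genes and 5 adjusted over the list alone (camera adjusted p = 6.63e-08; adjusted p = 0.0118 with an estimated correlation). Hey2, a target of Notch, differed by -2.86 ± 0.37 (adjusted p = 0.00133), and Jag1 and Sox17 were lower too. The endothelial identity list did not pass (camera adjusted p = 0.169; adjusted p = 0.686 with an estimated correlation). Of its 25 genes 1 was lower over all genes and adjusted over the list alone, Sox7, an endothelial transcription factor (-2.16 ± 0.29, adjusted p = 0.00162). The venous and lymphatic list did not pass either (camera adjusted p = 0.267; adjusted p = 0.531 with an estimated correlation). In it 2 of 11 were higher and 1 lower over all genes, and 2 higher and 4 lower adjusted over the list alone. Lyve1 and Stab2 were higher by 3.17 ± 0.37 (adjusted p = 0.000782) and 2.98 ± 0.35 (adjusted p = 0.000771), and Nr2f2, a venous transcription factor, differed by -2.45 ± 0.20 (adjusted p = 8.92e-05). Cell junction genes had 4 of 23 lower over all genes and 7 adjusted over the list alone (camera adjusted p = 4.24e-07; adjusted p = 0.0665 with an estimated correlation). Gjc1, a gap junction connexin, differed by -2.71 ± 0.32 (adjusted p = 0.000794) and Cdh2, N-cadherin, by -2.66 ± 0.28 (adjusted p = 0.000409). BMP and TGF-beta genes had 3 of 20 lower over all genes, and 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000386; adjusted p = 0.0306 with an estimated correlation). Id2, a target of BMP signalling, differed by -2.81 ± 0.31 (adjusted p = 0.000519) and Tgfb2, a TGF-beta ligand, by -1.92 ± 0.30 (adjusted p = 0.00448). On probe sets without a suffix Id2 did not pass (adjusted p = 0.944). The endothelial identity list passed as lower without 23GFP+ EC replicate 2 (adjusted p = 0.00697) or CD41+ HPC replicate 2 (adjusted p = 0.00554).

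Basement membrane genes had 2 of 15 lower in CD41+ HPC over all genes and 5 adjusted over the list alone (camera adjusted p = 0.00133; adjusted p = 0.375 with an estimated correlation). Lamb1 differed by -2.88 ± 0.24 (adjusted p = 0.000101). Endocardium genes had 2 of 8 lower over all genes and 5 adjusted over the list alone (camera adjusted p = 0.00019; adjusted p = 0.0198 with an estimated correlation). These were Tbx20, a cardiac T-box factor (-1.54 ± 0.26, adjusted p = 0.00602), and Npr3 (-1.31 ± 0.30, adjusted p = 0.0353). The nucleolus and Myc target list had 0 of 15 called by limma over all genes and 0 adjusted over the list alone (camera adjusted p = 0.119; adjusted p = 0.455 with an estimated correlation). Without 23GFP+ EC replicate 3 the basement membrane list no longer passed (adjusted p = 0.0661). The call of Npr3 ended without any 1 of 7 arrays, with an adjusted p of up to 0.124 (without 23GFP+ EC replicate 1), and with the mean of all probe sets (adjusted p = 0.507).

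The third comparison, CD41+ HPC against 23GFP- EC, set the ends of the transition named in the series title against each other. Runx1 was 8.72-fold higher in CD41+ HPC (3.12 ± 0.28, adjusted p = 0.000634) on the probe set used, and its other 5 probe sets gave 3.37, 2.14, 1.18, 0.88 and 0.47. Tubb1 was higher by 4.69 ± 0.39 (adjusted p = 0.000623), with mean levels of 8.5 in CD41+ HPC and 3.81 in 23GFP- EC, near the 25th percentile of the arrays. Slco4a1, an organic anion transporter, was higher by 4.44 ± 0.31 (adjusted p = 0.000345) on the probe set used, and its other one gave 0.83 and did not pass in its place (adjusted p = 0.0865). Csf1r, Plek and Myb were higher by 4.42 ± 0.43, 4.16 ± 0.37 and 4.06 ± 0.30 (adjusted p = 0.000849, 0.000623 and 0.000394), where the other probe sets of Csf1r gave 1.57 and 0.28. Gucy1a1, a subunit of the nitric oxide receptor, was higher by 3.91 ± 0.40 (adjusted p = 0.00122). Lower in CD41+ HPC were Cyp26a1, which degrades retinoic acid (15.6-fold, -3.96 ± 0.25, adjusted p = 0.000254), Foxc2 (-3.48 ± 0.31, adjusted p = 0.000623) and Npr3 (-3.07 ± 0.30, adjusted p = 0.000926). Of 18194 genes 420 passed, 174 higher and 246 lower, and 408 of them differed at least 2-fold. The count was 88, 105 or 128 without 23GFP- EC replicate 1, 2 or 3, 236 or 223 without CD41+ HPC replicate 1 or 3 and 705 without 23GFP+ EC replicate 2. It was 187 with a replicate block, 644 in a fit of these 6 arrays alone and 1121 with array weights. The share of called genes that were higher, 41.4 percent, was 31.2 to 60.2 percent over the alternatives, so the excess of lower genes turned in 7 of 21. It was 60.2, 51.4 and 52.3 percent without 23GFP- EC replicates 1, 2 and 3, 51.3 and 50.2 percent without CD41+ HPC replicates 1 and 3, 51.3 percent with a replicate block and 50.1 percent without the 2 arrays of narrowest spread. Of 41 called genes followed through the alternatives, 15 were called in all of them. Calls were lost in 23, 21 and 18 without 23GFP- EC replicates 1, 2 and 3, in 12, 10 and 13 without CD41+ HPC replicates 1, 2 and 3, in 5 without 23GFP+ EC replicate 1 and in 11 with a replicate block. Mean levels in 23GFP- EC of Ptprc (3.03) and Itgb2 (4.16), like that of Tubb1, lay under 4.25 and are not known to lie above background. Of 41 called genes under the naming rule with several probe sets, 22 had another one with under 0.5 of the difference used. Of the genes given here these are Afp, Coro1a, Csf1r, Jag1, Lamb1, Lyz1, Nr2f2, Ptprc, Runx1, Slco4a1, Socs3, Sox7, Sox17 and Tmem100, and in Afp and Nr2f2 the sign turned (0.08 and 0.02).

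Haematopoietic lists were higher in CD41+ HPC than in 23GFP- EC. Of the sorting markers, 2 of 4 were higher over all genes, and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00751; adjusted p = 0.171 with an estimated correlation). Ptprc was higher by 2.61 ± 0.56 (adjusted p = 0.0416), Itga2b differed by 0.57 ± 0.21 (adjusted p = 0.248) and Cdh5 by -0.99 ± 0.27 (adjusted p = 0.0982). Haemogenic endothelium genes had 6 of 16 higher and 1 lower over all genes, and 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.54e-10; adjusted p = 0.0382 with an estimated correlation). Gfi1 differed by 3.30 ± 0.40 (adjusted p = 0.00345). Haematopoietic transcription factors had 8 of 21 higher and 1 lower over all genes, and 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.19e-10; adjusted p = 0.0293 with an estimated correlation). Nfe2 differed by 3.18 ± 0.24 (adjusted p = 0.000422). In the pan-haematopoietic list 11 of 23 were higher over all genes, and 16 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.23e-14; adjusted p = 0.0243 with an estimated correlation). Itgb2, a leukocyte integrin chain, differed by 3.08 ± 0.45 (adjusted p = 0.00794) and Coro1a, an actin regulator of leukocytes, by 2.97 ± 0.27 (adjusted p = 0.000634). Ptprc lost its call without any 1 of 6 arrays, with an adjusted p of up to 0.155 (without 23GFP- EC replicate 2), and with array weights Cdh5 passed as lower (adjusted p = 0.0179). On probe sets without a suffix for shared sequence Ptprc and Coro1a did not pass (adjusted p = 0.683 and 0.409). The list of sorting markers did not pass without the dimmest 40 percent of genes (adjusted p = 0.106).

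Erythroid genes had 3 of 20 higher over all genes and 3 adjusted over the list alone (camera adjusted p = 2.05e-05; adjusted p = 0.107 with an estimated correlation). They were Nfe2, Gata1 (2.50 ± 0.37, adjusted p = 0.00869) and Klf1 (1.96 ± 0.39, adjusted p = 0.0301). Megakaryocyte and platelet genes had 6 of 19 higher over all genes and 7 adjusted over the list alone (camera adjusted p = 4.04e-09; adjusted p = 0.0336 with an estimated correlation). Itgb3 differed by 3.33 ± 0.51 (adjusted p = 0.00967). Myeloid genes had 7 of 19 higher over all genes and 8 adjusted over the list alone (camera adjusted p = 3.25e-08; adjusted p = 0.0262 with an estimated correlation). They included Lyz1, a lysozyme (3.38 ± 0.68, adjusted p = 0.0305; 2.63 and 0.27 on its other probe sets), and Mpo, myeloperoxidase (2.54 ± 0.44, adjusted p = 0.0173). Nucleolus and Myc target genes were higher as a list (camera adjusted p = 5.95e-06; adjusted p = 0.0589 with an estimated correlation). By limma 0 of 15 were called over all genes and 2 adjusted over the list alone, and Gnl3, a nucleolar GTPase, differed by 0.67 ± 0.18 (adjusted p = 0.0975). Gata1, Klf1, Itgb3 and Mpo lost their calls without single arrays, with adjusted p of up to 0.0594, 0.143, 0.069 and 0.0867 without 23GFP- EC replicate 1. Lyz1 did so with up to 0.127 without 23GFP- EC replicate 3, and on probe sets without a suffix (adjusted p = 0.823).

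Endothelial lists were lower in CD41+ HPC. Endothelial identity genes had 4 of 25 lower over all genes and 15 adjusted over the list alone (camera adjusted p = 5.26e-18; adjusted p = 0.0336 with an estimated correlation). Emcn, the sialomucin endomucin, differed by -2.43 ± 0.45 (adjusted p = 0.0209), Sox7 by -1.91 ± 0.29 (adjusted p = 0.00939) and Eng, a co-receptor for TGF-beta, by -1.0 ± 0.20 (adjusted p = 0.0316). Arterial and Notch genes had 6 of 19 lower over all genes and 15 adjusted over the list alone (camera adjusted p = 7.14e-15; adjusted p = 0.00355 with an estimated correlation). Sox17 differed by -1.77 ± 0.31 (adjusted p = 0.0171), Efnb2, an arterial ephrin, by -1.61 ± 0.33 (adjusted p = 0.0357) and Jag1 by -1.52 ± 0.25 (adjusted p = 0.0129). Venous and lymphatic genes had 4 of 11 lower over all genes and 9 adjusted over the list alone (camera adjusted p = 1.26e-12; adjusted p = 0.0178 with an estimated correlation). Nr2f2 differed by -1.87 ± 0.20 (adjusted p = 0.00173) and Stab2 by -1.65 ± 0.35 (adjusted p = 0.0387). Nr2f2 kept its call without any 1 array. The others lost theirs, with adjusted p of up to 0.121 for Emcn, 0.069 for Sox7, 0.185 for Eng, 0.102 for Sox17, 0.185 for Efnb2, 0.0875 for Jag1 and 0.196 for Stab2 without 23GFP- EC replicate 1. With the mean of all probe sets Jag1 and Nr2f2 did not pass (adjusted p = 0.078 and 0.13).

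Adhesion, matrix and signalling lists were also lower in CD41+ HPC. Cell junction genes had 5 of 23 lower over all genes and 16 adjusted over the list alone (camera adjusted p = 5.26e-18; adjusted p = 0.0178 with an estimated correlation). Cdh2 differed by -2.65 ± 0.28 (adjusted p = 0.00136) and Gjc1 by -2.50 ± 0.32 (adjusted p = 0.005). Basement membrane genes had 3 of 15 lower over all genes and 9 adjusted over the list alone (camera adjusted p = 1.78e-10; adjusted p = 0.0987 with an estimated correlation). Lamb1 differed by -1.76 ± 0.24 (adjusted p = 0.00664) and Nid2, which crosslinks laminin, by -1.41 ± 0.22 (adjusted p = 0.0109). BMP and TGF-beta genes had 4 of 20 lower over all genes, and 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.25e-08; adjusted p = 0.0178 with an estimated correlation). Id3 differed by -1.66 ± 0.25 (adjusted p = 0.00951) and Smad6, an inhibitor of BMP signalling, by -1.26 ± 0.24 (adjusted p = 0.0234). Endocardium genes had 3 of 8 lower over all genes and 4 adjusted over the list alone (camera adjusted p = 8.53e-06; adjusted p = 0.0178 with an estimated correlation). They included Npr3 and Tmem100, a target of BMP signalling in vessels (-2.28 ± 0.40, adjusted p = 0.0175). Nid2, Id3, Smad6 and Tmem100 lost their calls without single arrays, with adjusted p of up to 0.0784, 0.0664, 0.139 and 0.109 without 23GFP- EC replicate 1.

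Endoderm genes, of which 15 of 17 lay above the overall median level in 23GFP- EC and 10 in CD41+ HPC, had 4 genes lower in CD41+ HPC than in 23GFP- EC over all genes and 7 adjusted over the list alone (camera adjusted p = 4.90e-11; adjusted p = 0.129 with an estimated correlation). Ttr differed by -3.48 ± 0.55 (adjusted p = 0.0115) and Afp, alpha-fetoprotein, by -3.06 ± 0.55 (adjusted p = 0.0202). The Hox list was lower by camera (adjusted p = 2.61e-06; adjusted p = 0.0198 with an estimated correlation). It had 0 of 23 called by limma over all genes and 5 lower adjusted over the list alone. Mesenchyme and mesoderm genes had 2 of 18 lower over all genes and 3 adjusted over the list alone (camera adjusted p = 1.39e-05; adjusted p = 0.0336 with an estimated correlation), Foxc2 among them. In the epithelium and trophoblast list 0 of 9 were called by limma over all genes, and 3 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0201; adjusted p = 0.256 with an estimated correlation). That list had an adjusted p of 0.117 without CD41+ HPC replicate 2 and 0.0854 without 23GFP- EC replicate 3, and of 0.104 without the dimmest 40 percent of genes. Ttr and Afp lost their calls without single arrays, with adjusted p of up to 0.0618 and 0.0923 without 23GFP- EC replicate 3, and Afp on probe sets without a suffix (adjusted p = 0.166).

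Across the 3 populations together, 1034 genes differed by limma's moderated F-test. Genes highest in 23GFP+ EC, higher than in either other population, numbered 167, where independent lists would overlap by 5.92. They included Tfap2c, Prl4a1 (-4.75 ± 0.37 in CD41+ HPC against 23GFP+ EC, adjusted p = 6.31e-05), Hoxa9 and Tbx4. Genes lowest in 23GFP+ EC numbered 88, where independent lists would overlap by 3.92, and included Hba-x, Klf1, Lyve1 and Stab2. Others were F5, coagulation factor V (-3.23 ± 0.36 then 3.23 ± 0.36, adjusted p = 0.00223 and 0.000579), and Nrg1, a neuregulin growth factor (-3.25 ± 0.23 then 3.08 ± 0.23, adjusted p = 0.00034 and 5.94e-05). Both differences use the same 3 arrays of 23GFP+ EC, so the lists are not independent. Cells or free RNA of other tissue in the 23GFP+ EC sort would also make genes highest there, which was not tested for the 167 genes. Only 1 gene fell in both steps, Npr3 (-1.76 ± 0.30 then -1.31 ± 0.30, the latter with an adjusted p of up to 0.124 without 1 array, 23GFP+ EC replicate 1). By limma 0 rose in both, and 30 fell and 24 rose in both at an unadjusted p under 0.05. Without 23GFP- EC replicate 1, 2 or 3 the F-test gave 522, 571 or 611 genes, the number highest was 48, 48 or 94 and the number lowest 42, 48 or 52. Without 23GFP+ EC replicate 1 the number highest was 259, and without 23GFP+ EC replicate 3 the number lowest was 54. With array weights the F-test gave 2106 genes, 350 were highest and 183 lowest, and with a replicate block the F-test gave 662.

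The position of 23GFP+ EC between both ends was measured on each gene that differed at least 2-fold between CD41+ HPC and 23GFP- EC, with 0 at the level of 23GFP- EC and 1 at that of CD41+ HPC. Over the 171 genes higher in CD41+ HPC the median position was 0.0555 (quartiles -0.183 to 0.418), and on the single arrays of 23GFP+ EC it was -0.0134, 0.154 and 0.0360. Simulated arrays in which 23GFP+ EC was unchanged gave 0.125, those at a position of 0.5 gave 0.487 and those at the level of CD41+ HPC gave 0.884. Over the 237 genes lower in CD41+ HPC the median was 0.261 (quartiles -0.135 to 0.690), with 0.192, 0.316 and 0.386 on the single arrays, beside 0.0804, 0.512 and 0.931 in the simulation. Without 23GFP- EC replicate 1, 2 or 3 the latter became -0.0444, -0.0185 or 0.158. Without CD41+ HPC replicate 1 or 3 it was 0.0732 or 0.105, and with ends measured on arrays not used to choose the genes it was -0.0664. It was -0.0850 for ends at least 2 apart and 0.381 with the mean of all probe sets. The median over higher genes became -0.0463 or -0.0458 without 23GFP- EC replicate 1 or 2 and -0.109 with such held-out ends, and 0.142 without the dimmest 40 percent of genes.

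**Figure D1:**
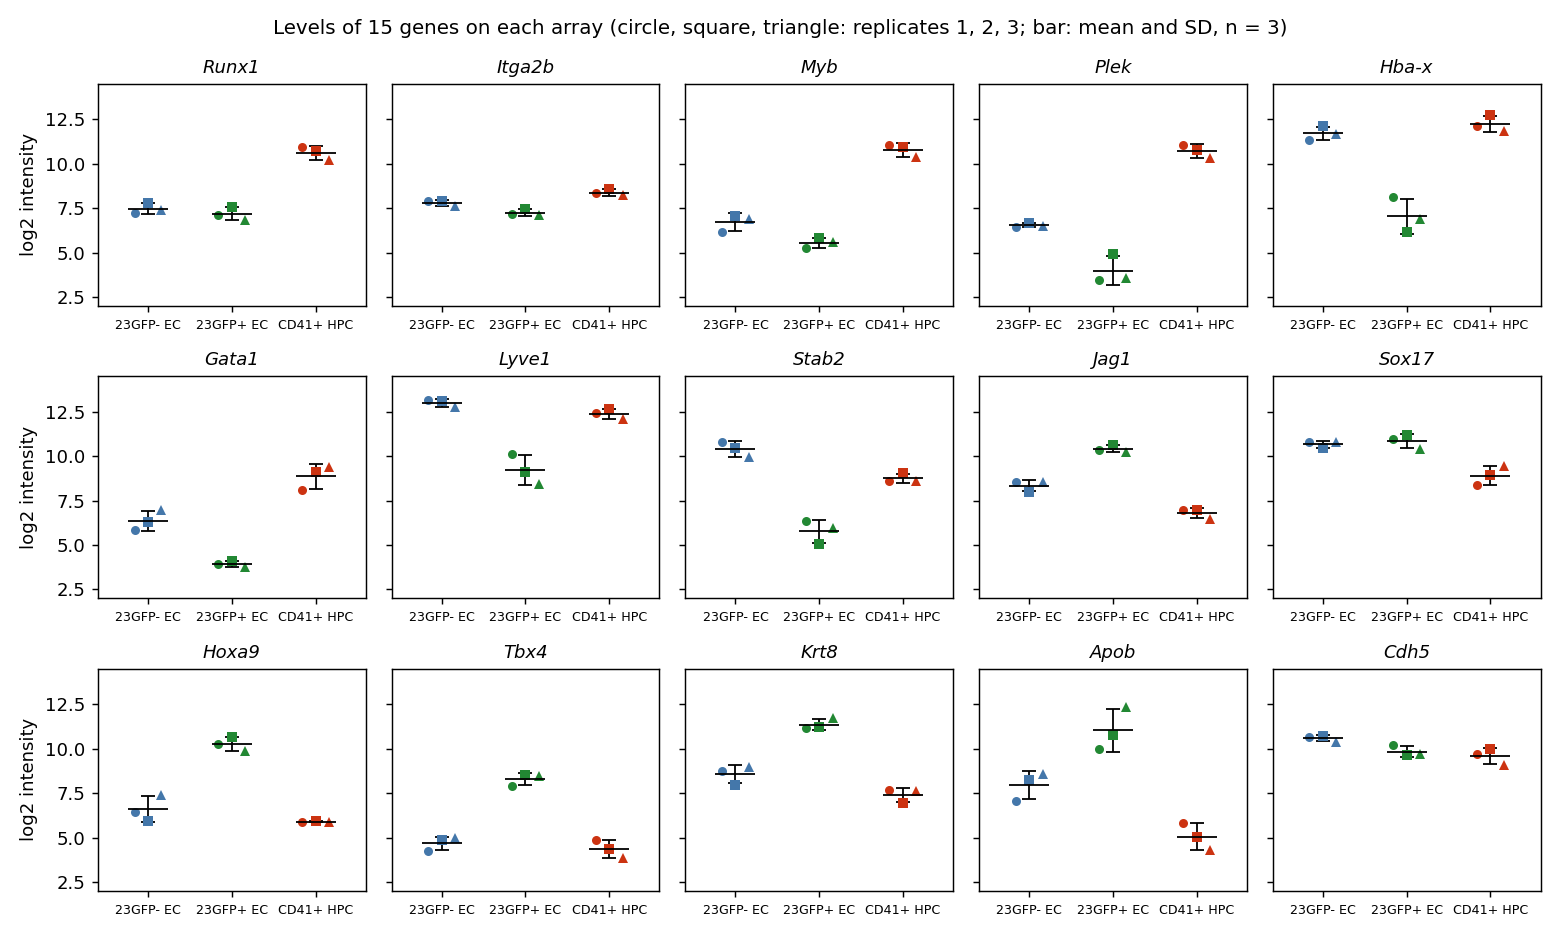
Log2 level of 15 genes on each of the 9 arrays, with circle, square and triangle for replicates 1, 2 and 3 and a bar for the mean and SD of each population (n = 3). On the probe set used the mean of Runx1 differs by -0.30 ± 0.28 (SE) in 23GFP+ EC against 23GFP- EC. It is 3.42 higher in CD41+ HPC than in 23GFP+ EC, while Jag1, Hoxa9, Tbx4, Krt8 and Apob are highest in 23GFP+ EC.

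**Figure D2:**
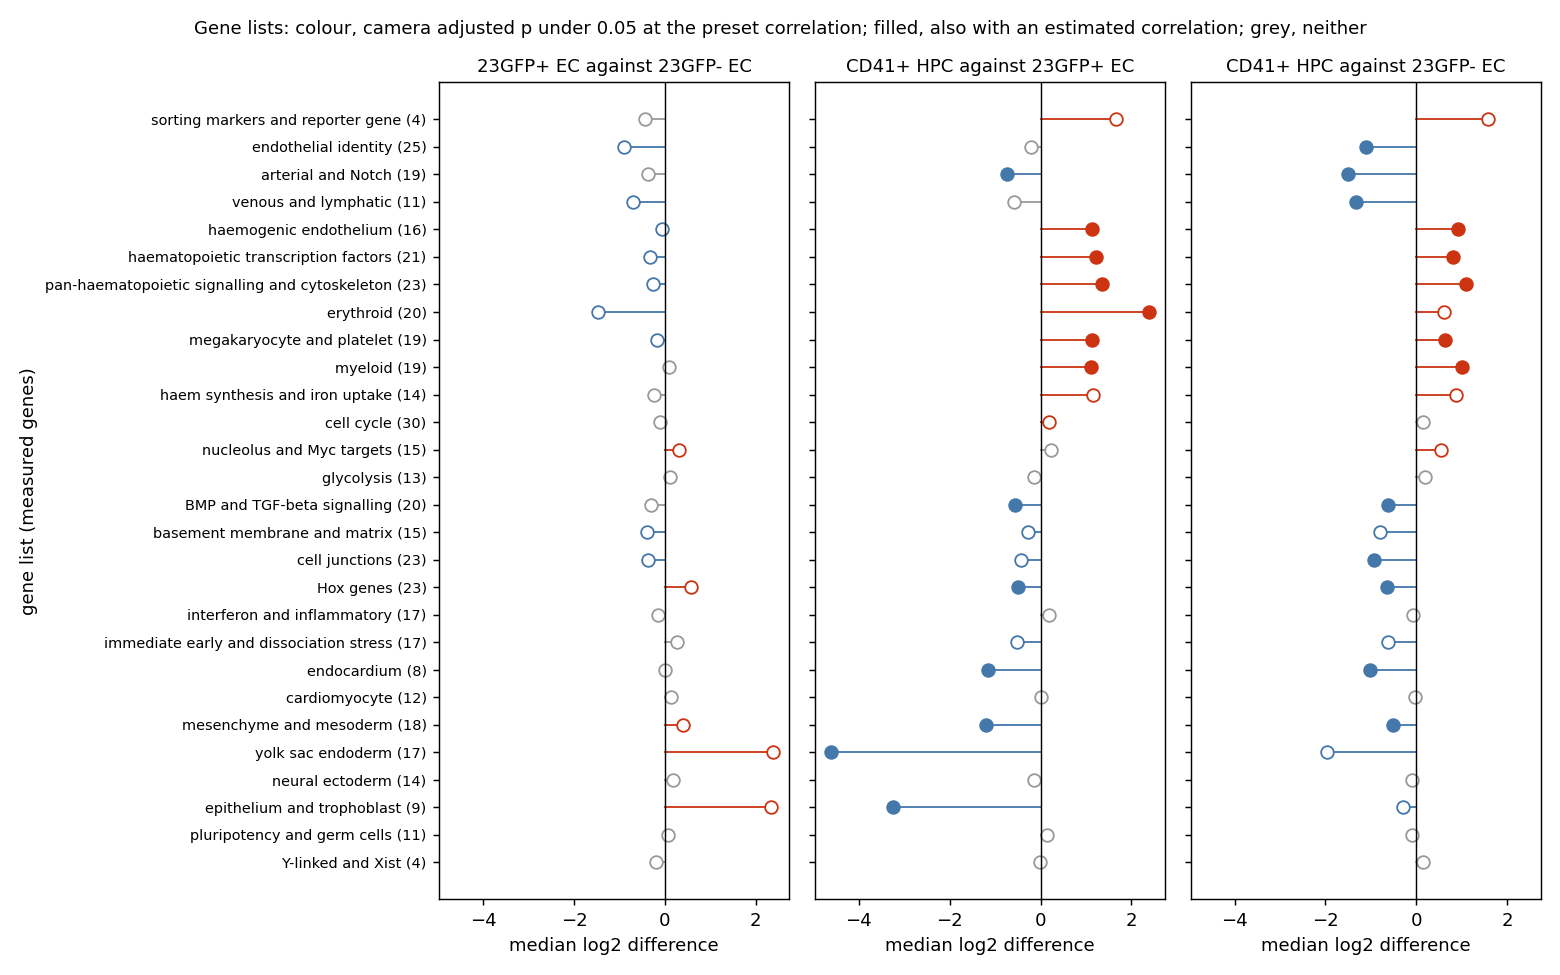
Median log2 difference of the members of each of the 28 gene lists in the 3 comparisons. Coloured points passed camera at an adjusted p under 0.05 with the preset correlation, filled ones also with an estimated correlation, and grey ones with neither; yolk sac endoderm genes reach 2.38 in 23GFP+ EC against 23GFP- EC, where 0 lists are filled.

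**Figure D3:**
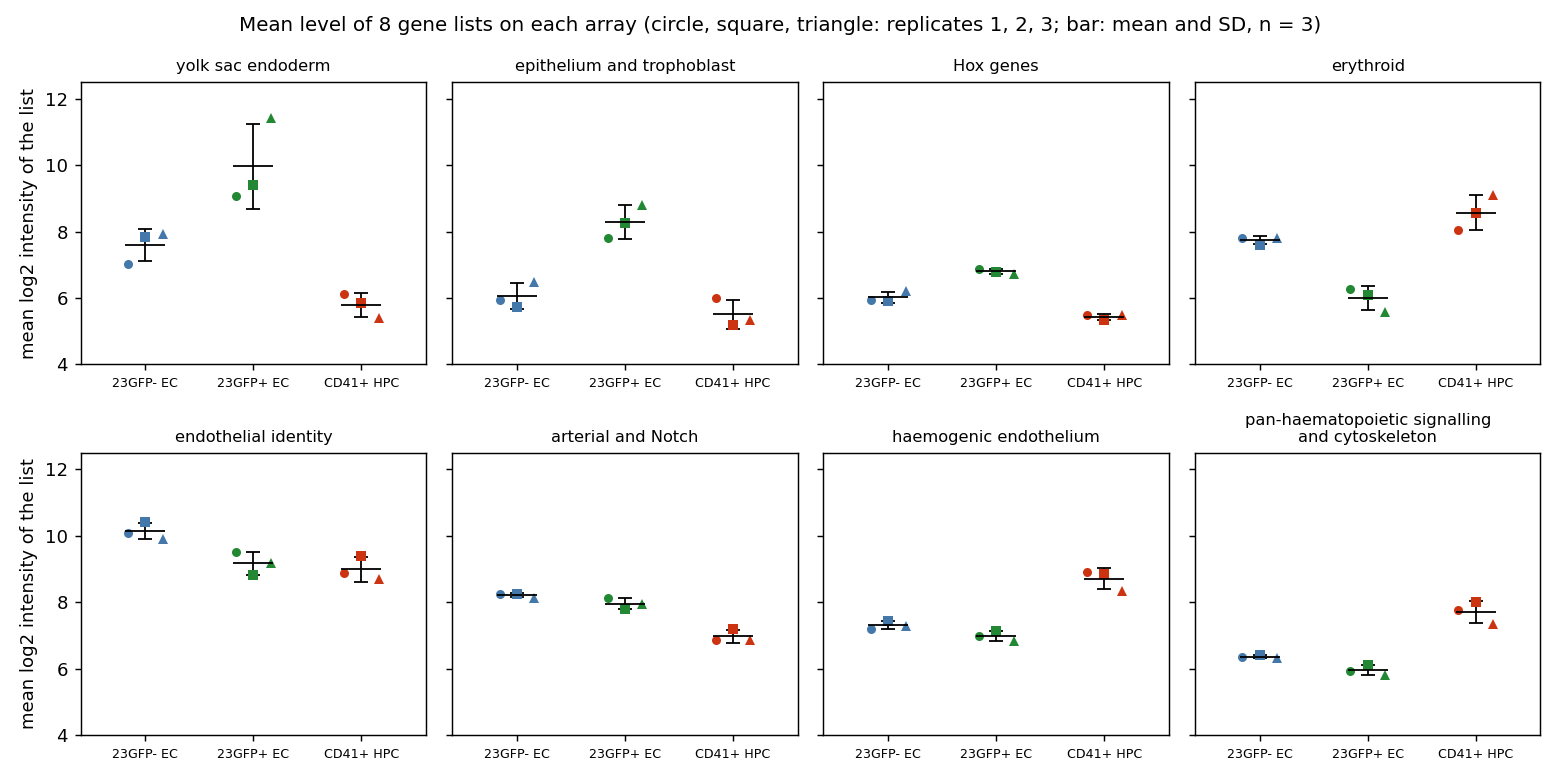
Mean log2 level of the members of 8 gene lists on each of the 9 arrays, grouped by population. The yolk sac endoderm list averages 9.97 in 23GFP+ EC, 7.60 in 23GFP- EC and 5.79 in CD41+ HPC.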

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

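The alternative without the 2 arrays of narrowest spread was chosen after seeing the data, and all others were planned. The cause of a change was not tested unless the alternative itself gives it. Of the 155 values of named genes, a turn of direction was counted only where the gene was called with or without the alternative. Probe sets without a suffix covered 129 of them and the fit without the dimmest genes 146. Counted this way directions held, with 2 exceptions. On probe sets without a suffix for shared sequence Ncam1 and Tnnt2 in CD41+ HPC against 23GFP+ EC moved from -2.15 and -1.51 to 0.19 and 0.21. Another probe set stands for each gene there. Which direction held more called genes did not hold: 41.2 to 59.2 percent were higher in 23GFP+ EC against 23GFP- EC and 31.2 to 60.2 percent in CD41+ HPC against 23GFP- EC, above 50 percent in 2 and 7 of 21 alternatives. In CD41+ HPC against 23GFP+ EC 33.1 to 42.8 percent were higher, above 50 percent in 0 of these. On probe sets without a suffix the calls of Socs3 against 23GFP+ EC and against 23GFP- EC ended (adjusted p = 0.949 and 0.953). With the mean of probe sets those of Uros, Ncam1 and Tnnt2 in CD41+ HPC against 23GFP+ EC (adjusted p = 0.108, 0.177 and 0.097), Klf6 and Socs3 in CD41+ HPC against 23GFP- EC (adjusted p = 0.083 and 0.0761) and Nes in 23GFP+ EC against 23GFP- EC (adjusted p = 0.133) ended. With array weights 1259, 1289 and 1121 genes passed in 23GFP+ EC against 23GFP- EC, CD41+ HPC against 23GFP+ EC and CD41+ HPC against 23GFP- EC, 2106 by the F-test, 350 highest and 183 lowest in 23GFP+ EC, and 430, 760 and 420 of the genes called before were among those of the 3 comparisons. Fits of only the 2 groups compared gave 452 in CD41+ HPC against 23GFP+ EC and 644 in CD41+ HPC against 23GFP- EC. With the replicate block, 187 genes passed in CD41+ HPC against 23GFP- EC and 662 by the F-test, where the block takes residual degrees of freedom, while the other comparisons gave 313 and 624. The block ended the calls of Apob, Dusp1, Fga, Gfi1b, Lamb1, Myc, Nes, Tfap2c and Zfp42 in 23GFP+ EC against 23GFP- EC (adjusted p = 0.0532 to 0.121) and of Atf3, Ncam1, Npr3, Tnnt2 and Zfp42 in CD41+ HPC against 23GFP+ EC (0.0551 to 0.105), where Ptprc passed (0.0466). In CD41+ HPC against 23GFP- EC it ended those of Afp, Crabp1, Emcn, Eng, Klf1, Klf6, Smad6, Socs3, Sox17, Stab2 and Tfrc (0.0529 to 0.108). With somite stage as a term the calls of Lamb1 (0.0691), Npr3 and Tnnt2 (0.0544 and 0.0645), and Lyz1, Ptprc and Socs3 (0.0538, 0.0574 and 0.0611) ended in the 3 comparisons in turn. The added alternative gave 527, 823 and 575 genes, 1106 by the F-test, 183 highest and 99 lowest. Centring and cyclic loess moved the median of all genes by less than 0.1 and every count by less than 1.5 times.

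Leaving out 1 array gave 119 to 539 genes in 23GFP+ EC against 23GFP- EC (119, 131 and 216 without 23GFP- EC replicates 1, 2 and 3, 256 without 23GFP+ EC replicate 3), 595 to 867 in CD41+ HPC against 23GFP+ EC, and 88 to 705 in CD41+ HPC against 23GFP- EC (88, 105 and 128 without 23GFP- EC replicates 1, 2 and 3, 236 and 223 without CD41+ HPC replicates 1 and 3, 705 without 23GFP+ EC replicate 2). Of the 119 genes called in 23GFP+ EC against 23GFP- EC without 23GFP- EC replicate 1, 118 were among the 433. The F-test gave 522 to 1202, the genes highest in 23GFP+ EC numbered 48 to 259 and those lowest 42 to 96. Where 1 group keeps 2 arrays, the fit pools the spread over all groups. The median position over genes higher in CD41+ HPC was -0.0463 to 0.0796 without 1 array, 0.142 without the dimmest genes and -0.109 with held-out ends. Over genes lower in CD41+ HPC it was -0.0444 to 0.308 without 1 array, 0.381 with the mean of probe sets, -0.0850 for ends at least 2 apart and -0.0664 with held-out ends (6 to 15 genes per pair of arrays).

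With an estimated correlation 0 lists passed camera in 23GFP+ EC against 23GFP- EC (14 with the preset one, 8 at an unadjusted p under 0.05), 13 in CD41+ HPC against 23GFP- EC (21) and 13 in CD41+ HPC against 23GFP+ EC (19). The other list alternatives gave 12 to 18 lists in 23GFP+ EC against 23GFP- EC, 19 to 22 in CD41+ HPC against 23GFP- EC and 18 to 19 in CD41+ HPC against 23GFP+ EC. With 3 arrays per group a simulated log2 change of 1 was recovered in 16.4 to 22.4 percent of genes.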

Other observations

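Haem synthesis and iron uptake genes were higher in CD41+ HPC than in 23GFP+ EC, 5 of 14 over all genes and 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.24e-07; adjusted p = 0.0918 with an estimated correlation). Alas2, the erythroid enzyme of the first step of haem synthesis, was higher by 2.47 ± 0.39 (adjusted p = 0.00425), Slc25a37, the mitochondrial iron importer, by 1.85 ± 0.35 (adjusted p = 0.0121) and Uros, another enzyme of the pathway, by 1.58 ± 0.34 (adjusted p = 0.0237, and up to 0.0805 without 23GFP+ EC replicate 1). In CD41+ HPC against 23GFP- EC 2 of 14 were higher over all genes and 4 adjusted over the list alone (camera adjusted p = 1.94e-05; adjusted p = 0.129 with an estimated correlation), Tfrc, the transferrin receptor, by 1.30 ± 0.27 (adjusted p = 0.0334, and up to 0.17 without 23GFP- EC replicate 1). In 23GFP+ EC against 23GFP- EC 0 of 14 passed by limma over all genes and 2 were lower adjusted over the list alone (camera adjusted p = 0.102; adjusted p = 0.531 with an estimated correlation), and the list passed without 23GFP+ EC replicate 3 (adjusted p = 0.0434). Immediate early genes were lower in CD41+ HPC than in 23GFP+ EC, 5 of 17 over all genes and 8 adjusted over the list alone (camera adjusted p = 4.63e-05; adjusted p = 0.139 with an estimated correlation). Atf3, a stress-induced transcription factor, was lower by -2.23 ± 0.46 (adjusted p = 0.0204, and 0.0681 without 23GFP+ EC replicate 1) and Socs3, an inhibitor of cytokine signalling, by -2.18 ± 0.38 (adjusted p = 0.00799). Against 23GFP- EC, 2 of 17 were lower over all genes and 4 adjusted over the list alone (camera adjusted p = 2.27e-05; adjusted p = 0.129 with an estimated correlation), Socs3 (-1.73 ± 0.38, adjusted p = 0.0452, and up to 0.203) and Klf6, a zinc-finger factor (-1.06 ± 0.23, adjusted p = 0.0413, and up to 0.206, both without 23GFP- EC replicate 1). Between both endothelial populations 1 of 17 was lower over all genes, Dusp1, a phosphatase (-1.20 ± 0.26, adjusted p = 0.0437, and up to 0.22 without 23GFP- EC replicate 1), and 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.560; adjusted p = 0.769 with an estimated correlation).

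Cell cycle genes had 0 of 30 called by limma in all 3 comparisons, over all genes and adjusted over the list alone. As a list they were higher in CD41+ HPC than in 23GFP+ EC (camera adjusted p = 0.0271; adjusted p = 0.15 with an estimated correlation), but not without 23GFP+ EC replicate 2 or CD41+ HPC replicate 2 (adjusted p = 0.164 and 0.177) or the dimmest 40 percent of genes (adjusted p = 0.0696), and the other comparisons gave adjusted p = 0.276 in 23GFP+ EC against 23GFP- EC and 0.189 in CD41+ HPC against 23GFP- EC (0.447 and 0.346 with an estimated correlation). Glycolysis genes had 1 of 13 called, Hk1, a hexokinase higher in CD41+ HPC than in 23GFP+ EC (1.30 ± 0.29, adjusted p = 0.0324, and up to 0.0967 without CD41+ HPC replicate 2), where 1 was higher and 1 lower adjusted over the list alone. Camera adjusted p was 0.368, 0.686 and 0.511 in 23GFP+ EC against 23GFP- EC, CD41+ HPC against 23GFP+ EC and CD41+ HPC against 23GFP- EC (0.681, 0.843 and 0.795 with an estimated correlation), and 0.0108 in the first without 23GFP+ EC replicate 2. Interferon and inflammatory genes gave 0.0722, 0.963 and 0.0815 in the same order (0.199, 0.963 and 0.134 with an estimated correlation), and passed as lower in the first without 23GFP- EC replicate 3 (adjusted p = 0.0360) and in the last without 23GFP- EC replicate 3 or CD41+ HPC replicate 2 (adjusted p = 0.0357 and 0.0495). Of 17, 1 was higher and 1 lower in the first, 1 higher and 2 lower in the second and 0 called by limma in the last over all genes, with the same numbers adjusted over the list alone except 2 lower in the last. B2m, a subunit of MHC class I, was lower in 23GFP+ EC than in 23GFP- EC (-1.53 ± 0.30, adjusted p = 0.0258) and higher in CD41+ HPC (1.27 ± 0.30, adjusted p = 0.0389), and Ifitm1, an interferon-induced membrane protein, was higher and then lower (1.51 ± 0.25 and -1.30 ± 0.25, adjusted p = 0.0127 and 0.0137). The calls of B2m ended without single arrays, with adjusted p of up to 0.133 (without 23GFP- EC replicate 2) and 0.13 (without CD41+ HPC replicate 1), and those of Ifitm1 with 0.0725 (without 23GFP- EC replicate 1) and 0.0572 (without CD41+ HPC replicate 3).

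Lists of other embryonic tissues gave few calls. Cardiomyocyte genes had 1 of 12 lower in 23GFP+ EC than in 23GFP- EC, Myh7, a myosin heavy chain (-2.47 ± 0.46, adjusted p = 0.0213, and up to 0.0924 without 23GFP- EC replicate 3), 1 lower in CD41+ HPC than in 23GFP+ EC, Tnnt2, a cardiac troponin (-1.51 ± 0.36, adjusted p = 0.0404, and up to 0.155 without CD41+ HPC replicate 3), and 0 by limma in the third comparison. Adjusted over the list alone 1 was lower, 2 lower and 1 higher, and 1 lower and 1 higher (camera adjusted p = 0.654, 0.686 and 0.797; 0.681, 0.713 and 0.795 with an estimated correlation). Neural ectoderm genes had 1 of 14 lower in the first comparison, Nes, an intermediate filament (-1.45 ± 0.27, adjusted p = 0.0207, and up to 0.113 without 23GFP- EC replicate 2), 2 lower in the second, Crabp1, which binds retinoic acid (-3.67 ± 0.44, adjusted p = 0.000898), and Ncam1, an adhesion molecule (-2.15 ± 0.45, adjusted p = 0.0228, and up to 0.0851 without CD41+ HPC replicate 1), and 1 in the third, Crabp1 (-2.19 ± 0.44, adjusted p = 0.0317, and up to 0.141 without 23GFP- EC replicate 2). Adjusted over the list alone 1 was higher and 1 lower in the first, and 2 lower in each of the others (camera adjusted p = 0.387, 0.0862 and 0.125; 0.447, 0.146 and 0.171 with an estimated correlation), and the third passed without 23GFP- EC replicate 1 (adjusted p = 0.0485). Pluripotency and germ cell genes had 1 of 11 called over all genes in the first and second comparisons, Zfp42, a zinc-finger gene of embryonic stem cells and trophoblast (1.93 ± 0.34 and -1.72 ± 0.34, adjusted p = 0.0159 and 0.0166, and up to 0.0931 without 23GFP- EC replicate 2 and 0.064 without CD41+ HPC replicate 2). Adjusted over the list alone 1 was higher and 1 lower, then 1 lower, and 0 by limma in the third (camera adjusted p = 0.654, 0.498 and 0.797; 0.681, 0.531 and 0.795 with an estimated correlation). Y-linked genes and Xist had 0 of 4 called by limma in all 3 comparisons, over all genes and adjusted over the list alone (camera adjusted p = 0.762, 0.833 and 0.976; 0.769, 0.843 and 0.977 with an estimated correlation). In CD41+ HPC against 23GFP+ EC the median and mean differed in sign for cardiomyocyte (0.01 and -0.07), pluripotency (0.14 and -0.22) and Y-linked and Xist genes (0.00 and 0.14), and for interferon genes the median and mean (0.19 and 0.00) lay above 0 while camera ranked the list as lower.

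The tests of the 3 patterns below were chosen after the results had been seen, while the splits of the arrays were planned before. The lists of endoderm genes and of epithelium and trophoblast genes passed camera as higher in 23GFP+ EC than in 23GFP- EC (adjusted p = 5.08e-17 and 2.24e-12), but not with an estimated correlation (adjusted p = 0.134 and 0.0699). For the endoderm genes the narrow spread of the array of 23GFP+ EC replicate 2 is argued against as the cause: without it the median of the 17 was 2.95 (2.38 with it). Cells or free RNA of yolk sac endoderm in the 23GFP+ EC sort remain a candidate source of the endoderm genes. Of these 17 genes 16 were highest on replicate 3, as from 1 source, although the gate on VE-cadherin should remove endoderm cells. The epithelium and trophoblast genes averaged 7.79, 8.26 and 8.81 on replicates 1, 2 and 3 of 23GFP+ EC. Their source, trophoblast cells or RNA included, was not tested. Afp and Ttr had the highest probe-set levels of the 17 genes, which need not rank abundance. They stood at 13.1 ± 0.38 and 12.7 ± 0.65 (SD, n = 3) in 23GFP+ EC and 11.2 ± 0.38 and 10.7 ± 0.30 in 23GFP- EC. Of the 17 genes 0 are in another list and 15 lay above the overall median in 23GFP- EC too, and a difference between the populations themselves stays open and untested.

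In the Hox list 6 of 23 genes were called higher in 23GFP+ EC (camera adjusted p = 6.92e-05; adjusted p = 0.0699 with an estimated correlation). The endoderm source is argued against for these 6 as a set. They were lower on replicate 3 than on the other arrays of 23GFP+ EC by a median of -0.46, where endoderm genes were higher by 2.13. The 6 were called by limma, which favours genes with little spread between arrays, so their shift alone cannot decide this. All 23 Hox genes, called or not, averaged 6.88, 6.79 and 6.74 on replicates 1, 2 and 3 of 23GFP+ EC. The endoderm genes averaged 9.08, 9.39 and 11.4 there. Hoxd9, at 1.42, is the exception that stays open. Cells or free RNA of other mesoderm in the sort cannot be told apart from a Hox difference in the endothelium itself. Adjusted over the list alone 5 of 18 mesenchyme and mesoderm genes were higher, neither most nor none of them. Of their differences 17 lay above 0 and 1 below (median 0.40). The gate on VE-cadherin should remove mesoderm cells without it. Foxc2 and Col1a2 had the highest probe-set levels of the 18, which need not rank abundance. They stood at 9.35 ± 0.29 and 9.24 ± 0.90 (SD, n = 3) in 23GFP+ EC and 9.12 and 8.73 in 23GFP- EC. Of those 18 genes 0 are in another list, 12 lay above the overall median in 23GFP- EC, and Tbx4, the one with the largest difference, was 0.23 higher on replicate 3 than on the other arrays. A difference between the populations themselves stays open and untested.

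The lists of erythroid genes, haematopoietic transcription factors and pan-haematopoietic genes passed camera as lower in 23GFP+ EC than in 23GFP- EC (adjusted p = 2.14e-17, 5.76e-07 and 0.00113). With an estimated correlation they did not (adjusted p = 0.0699, 0.0898 and 0.249), and the myeloid list passed with neither (adjusted p = 0.0572 and 0.331). Dilution of the 23GFP+ EC sort by other cells cannot be told apart from a difference between the populations. Erythroid genes were not the only ones lower, since 24 of the 25 endothelial differences also lay below 0. All 20 erythroid genes had a median of -1.48 (quartiles -2.52 to -1.19) and the 25 endothelial genes one of -0.90 (quartiles -1.26 to -0.63, range -2.72 to 0.26), so the medians differed by -0.58 while the quartiles overlap. Erythroid cells or their RNA in the 23GFP- EC sort cannot be told apart from a difference between the populations. Of the 20 erythroid genes 8 were highest on the same array of 23GFP- EC, and the list's median shift between these arrays, 0.24, leaves too little variation to follow a source. Hba-x and Hbb-bh1 stood at 11.7 and 13.1 in 23GFP- EC and 12.2 and 13.5 in CD41+ HPC. The gate against Ter119 should remove erythroid cells that carry it but not those without it. Of the 20 genes 17 lay above the overall median in 23GFP- EC, and 5 are in another list. An exchange of the labels of both endothelial sorts cannot be told apart from the labels as given, because Runx1, the driver of the reporter only from knowledge outside the labels, differed by -0.30 ± 0.28, and a difference between the populations stays open and untested.

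The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. The real splits gave 433, 835 and 420 genes in 23GFP+ EC against 23GFP- EC, CD41+ HPC against 23GFP+ EC and CD41+ HPC against 23GFP- EC, each reached by 1 split, the real one, where the highest other gave 0 by limma. For gene lists 2, 1 and 1 of the 10 splits passed as many lists as the real 14, 19 and 21, and the highest others gave 14, 17 and 15. Over the 9 arrays, 1 of 100 seeded splits, the real one, gave as many genes in each case. The counts were 1034 genes by the F-test (highest other 175), 167 highest in 23GFP+ EC (68) and 88 lowest (60). A random grouping of the arrays is thus an unlikely source of counts this large. That holds for the counts only and does not place any single gene among them beyond chance.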
